A study of Mus musculus with 12 samples.

How the data were processed

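The libraries came from conditionally immortalised mouse tubular epithelial cells. Per the labels' protocols, such cells carry an SV40 large T antigen, grow at 33 °C with 10 ng/mL interferon γ, and were moved to 37 °C without it for 7 days. They carried a mock construct or an Nnmt expression construct with puromycin selection, and TGFβ was given at 10 ng/mL for 48 h. From 100 ng of RNA, libraries were made with a 3' tag method (QuantSeq forward), which yields about 1 tag per transcript near its 3' end, so counts are not scaled by transcript length. No molecular identifiers are stated, so counts are of reads, not of molecules.

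The deposited file holds raw counts of reads per gene in 1 table, with 12 columns, 1 for each library. Per the submitters' processing notes, STAR and HTSeq were used, with versions not given, and the human build GRCh38 is named. The gene identifiers in the table are mouse Ensembl identifiers, so the mouse build, the annotation release and the strand setting are not given in the sources used here, and no coordinates are printed. Reads that could not be told between overlapping genes or antisense partners are therefore uncertain. The 5 HTSeq totals for reads given to no gene were left out of library sizes and tests. Reads outside genes made up 26.4 to 28.79% of the table and ambiguous reads 0.6 to 0.68%. Symbols came from a GENCODE M21 table of names, which matched 55141 of 55487 identifiers (99.4%), and 107 identifiers with a shared symbol were named by identifier. Gene lengths and GC for 1 check came from the mouse transcripts of the reference given.

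Samples were grouped by their titles. All 12 libraries entered 1 fit with a mean for each group, in edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 12897 and removed 42590. Libraries were scaled by TMM, with factors from 0.981 to 1.011, and tested with the robust quasi-likelihood F test and Benjamini-Hochberg adjustment over all genes tested, at 0.05. The common dispersion was 0.0331. The contrasts were labelled Nnmt-OE against mock without and with TGFβ, TGFβ against none in mock and in labelled Nnmt-OE, and the interaction. CPM are given as mean ± SD of 3 libraries and log2 fold changes with the SE of the model.

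26 gene lists were fixed before the data were examined, with 829 different genes of which 586 passed the filter on low counts and were tested. Members called measured below are those tested. Only 2 list symbols were missing from the count table, and the other untested genes fell below the filter. That left 12 of 44 proximal tubule genes, 4 of 27 of other nephron segments and 20 of 47 junction and keratin genes. They cover TGFβ-SMAD response, Id genes, extracellular matrix, mesenchymal and contractile, junction and keratin, proximal tubule, other nephron segments, tubular injury, p53 and arrest, senescence-associated secretory phenotype, cell cycle, NAD metabolism, one-carbon metabolism, interferon, NRF2, unfolded protein, fatty acid oxidation, cholesterol, hypoxia, YAP-TEAD, 4 other cell types and 2 signs of RNA quality. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 26 lists of a comparison. Calls were counted over all genes tested and adjusted over the list alone. Of the lists called, 3 of 4 for the construct without TGFβ, 2 of 6 with TGFβ, and 11 of 15 and 11 of 16 for TGFβ in mock and labelled Nnmt-OE cells held with an estimated correlation. Where a list call has no such p beside it, it was among those that held.

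Named genes followed a rule set before the data were examined. It took Nnmt, the 10 genes with the largest rise and fall among those called with at least 10 CPM in the higher group, no overlap of replicates and a proper symbol, up to 4 members of each list with the smallest adjusted p, and up to 2 with their values where fewer than 2 passed. Some genes that the rule covers are not reported here. Cdkn1a, Cdkn2a, and Trib1 and Ccn1 with TGFβ are named outside that rule, and so are genes outside the lists in the closing section, chosen after their values were seen.

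Alternatives changed 1 choice at a time: RLE scaling, library totals, DESeq2 1.42.0, limma-voom, no filter or a stricter filter (1 CPM in 3 libraries and 50 counts in total), a block for the replicate number, each library left out, Nnmt left out, the groups compared only, a 2-fold threshold, an estimated correlation and fry. The fit without the 3 libraries that stand apart was added after the data were seen. The median log2 fold change of all genes stayed within 0.02 of 0 under each scaling.

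The test was checked on simulated counts for 12897 genes with 200 changed. For labelled Nnmt-OE against mock without TGFβ, it recovered 22.5% of genes changed 1.5-fold, 63.9% at 2-fold and 85.3% at 4-fold, and 5.8% of its calls were false. With TGFβ the shares were 29, 64.7 and 82.9% (4.8% false). For TGFβ in mock cells they were 25.7, 57.4 and 82.6% (2.7% false) and in labelled Nnmt-OE cells 46.2, 56.9 and 87.1% (3.8% false). The list test was checked only for labelled Nnmt-OE against mock without TGFβ. There the matrix list, shifted 1.5-fold, was called in 10 of 10 draws, and 0 lists in 10 unchanged draws. Genes were drawn independently of each other. These draws therefore show neither the false calls of lists whose genes vary together nor the recovery of smaller shifts.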

Results

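Messenger RNA was measured in mouse tubular epithelial cells, the cells that line the kidney tubule, carrying either a mock construct or a construct for expression of nicotinamide N-methyltransferase (Nnmt), an enzyme that transfers a methyl group from S-adenosylmethionine to nicotinamide. Cells of each kind were left untreated or given transforming growth factor β (TGFβ), the cytokine most widely used to drive fibrotic change in culture, at 10 ng/mL for 48 h. The 12 libraries formed 4 groups of 3. Reads assigned to genes numbered 5745122, 4733846 and 6072745 in mock replicates 1 to 3, 7168925, 7247413 and 5693417 in mock with TGFβ, 5573957, 6753611 and 5420532 in Nnmt-OE, and 5992130, 5865442 and 4845677 in Nnmt-OE with TGFβ. Nothing in the labels says whether the 3 replicates of a group were separate cultures, so p-values measure the spread between these samples, which may be technical. For a gene at 10 CPM (its count scaled to the library size) or more, the 95% interval of a log2 fold change between 2 groups reached 0.35 to either side at the median.

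Nnmt was measured first, since it checks the labels. Nnmt (ENSMUSG00000032271) stood at 20.3 ± 3.8 CPM in mock cells and 25.3 ± 2.9 CPM in cells labelled Nnmt-OE (mean ± SD, n = 3). With TGFβ it stood at 30.3 ± 2.8 CPM in mock and 27.6 ± 5.8 CPM in Nnmt-OE. The Nnmt-OE to mock fold was 1.25 without TGFβ (95% interval 0.92 to 1.69, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.897) and 0.91 with TGFβ (0.68 to 1.22, edgeR adjusted p = 0.998). TGFβ gave Nnmt a fold of 1.49 in mock (1.11 to 2.02, edgeR adjusted p = 0.206) and 1.09 in Nnmt-OE (0.81 to 1.47, edgeR adjusted p = 0.9). The libraries count tags near the 3' end of a transcript, and the labels do not describe the 3' end of the construct. A construct without the native 3' end would not be counted, and the Nnmt count then checks nothing. The construct groups are therefore called labelled Nnmt-OE, and every direction given for them rests on that label.

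**Figure D1:**
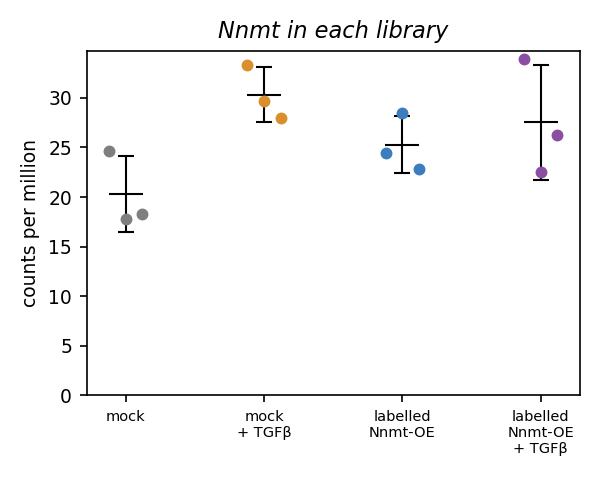
Nnmt in CPM (y axis, from 0) in each of the 12 libraries, by group (x axis), with points for libraries and bars for the mean ± SD of 3. The group means lie between 20.3 and 30.3 CPM and the ranges of labelled Nnmt-OE and mock overlap.

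The replicates of each group differed by more than sampling noise, and no library repeated another. The first 3 principal components held 15, 12.8 and 11.7% of the variance. On the first, all TGFβ libraries lay between 10 and 33.8 and all untreated ones between -45.8 and -3.9. Mock replicate 1, mock with TGFβ replicate 3 and Nnmt-OE with TGFβ replicate 3 each stood apart on at least 1 of them. The library codes of the construct groups do not interleave with those of the mock groups, so a difference in handling between construct and mock libraries cannot be told apart from the construct. Within mock and within Nnmt-OE, the codes of TGFβ and untreated libraries do not interleave either. A difference in handling between those libraries likewise cannot be told apart from TGFβ.

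The first comparison asked what the Nnmt construct changed in untreated cells. In cells labelled Nnmt-OE 5 genes were higher and 0 lower, and such genes are known to be switched on within minutes to hours of a stimulus. Egr1, a zinc-finger transcription factor, rose 2.34-fold (log2 1.23 ± 0.11 SE, edgeR adjusted p = 3.56e-10), from 113.7 ± 7.3 to 266.6 ± 13.7 CPM (SD, n = 3). Dusp1, a phosphatase that switches off MAP kinases, rose 2.36-fold, and Trib1, a pseudokinase that steers protein degradation, rose 1.74-fold (edgeR adjusted p = 0.00119 for each). Ccn1, a matricellular protein induced by YAP, rose 1.35-fold (edgeR adjusted p = 0.0133), and Ier3, an immediate-early gene linked to survival, rose 1.53-fold (edgeR adjusted p = 0.033). For each of them the 3 values in labelled Nnmt-OE did not overlap the 3 mock values, which chance gives, counting either direction, in 10% of genes.

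Across the lists fixed beforehand, 4 of 26 shifted upward in labelled Nnmt-OE cells without TGFβ. Among 24 measured TGFβ-SMAD response genes, 0 rose over all genes tested and 2 did when adjusted over the list alone, namely Junb (0.45 ± 0.12 log2 ± SE), an AP-1 subunit, and Pdgfb (0.32 ± 0.10), a growth factor. 18 of the 24 had positive values, with a median log2 fold change of 0.15 (camera adjusted p = 0.00312, and adjusted p = 0.042 with an estimated correlation). Of 35 genes for the senescence-associated secretory phenotype, 0 rose over all genes and 1 when adjusted over the list alone, the chemokine gene Cxcl1 (0.60). The EGF receptor ligand gene Hbegf stood at 0.37, and the list median was 0.14 (camera adjusted p = 0.0033, and 0.042 as adjusted p with an estimated correlation). Of 25 YAP-TEAD targets, Ccn1 rose, over all genes and adjusted over the list alone, and 24 did not pass, Gadd45b among them at 0.49 (median 0.12, camera adjusted p = 0.00312, adjusted p = 0.042 with an estimated correlation). Of 55 cell cycle genes, 0 passed by either adjustment. Their median was 0.08, with Hmgb2 at 0.39 and the centromeric histone gene Cenpa at 0.28 (camera adjusted p = 0.0326, adjusted p = 0.192 with an estimated correlation).

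Pathways around the enzyme itself gave no call in this comparison. The 22 measured genes of NAD metabolism had 0 calls by either adjustment and a camera adjusted p of 0.775, with Ppargc1a, a coactivator of mitochondrial genes, at 0.24 and Parp2 at -0.37. The 34 genes of the methyl cycle and one-carbon metabolism had 0 calls by either adjustment and a camera adjusted p of 0.524. Mat2a, which makes S-adenosylmethionine, stood at 0.29 and the folate enzyme gene Mthfd1 at 0.48. Of 39 genes for p53 and cell-cycle arrest, 0 passed over all genes, and 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.144). The antiproliferative gene Btg2 stood at 0.45 and the kinase gene Plk2 at 0.36. The cell-cycle inhibitor Cdkn1a measured 1584 ± 363 CPM in mock and 1920 ± 149 CPM in labelled Nnmt-OE, and Cdkn2a measured 729.4 ± 106 and 627.2 ± 59.3 CPM. Ribosomal protein messengers, a list kept as a sign of RNA quality, had a median of -0.08 and 4 lower calls adjusted over the list alone, with Rps9 at -0.39 and Rpl32 at -0.30, against 0 over all genes (camera adjusted p = 0.13). The water channel gene Aqp1, at 0.27, was the 1 proximal tubule gene called when adjusted over the list alone. The median, mean and test differed in sign for extracellular matrix, mesenchymal, proximal tubule, interferon, unfolded protein and fibroblast genes, none of which was called here.

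The count of 5 fell to 3 without mock replicate 3, without Nnmt-OE replicate 1 and in the fit of these groups alone. Ier3 kept its call in 4 of 12 fits without 1 library (highest adjusted p 0.62, without Nnmt-OE replicate 1) and Ccn1 in 8 (highest 0.208, without Nnmt-OE replicate 2). The YAP-TEAD call ended without mock replicate 3 (adjusted p = 0.0604) and the cell cycle call without mock replicate 1 (0.221), mock replicate 3 (0.0658) or Nnmt-OE replicate 3 (0.2). Without the immediate-early genes of a list drawn up after these calls were seen, which holds Junb, Cxcl1, Hbegf, Ccn1 and Gadd45b, the TGFβ-SMAD and secretory calls ended (camera adjusted p = 0.0663 each) and so did the YAP-TEAD call (0.155).

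**Figure D2:**
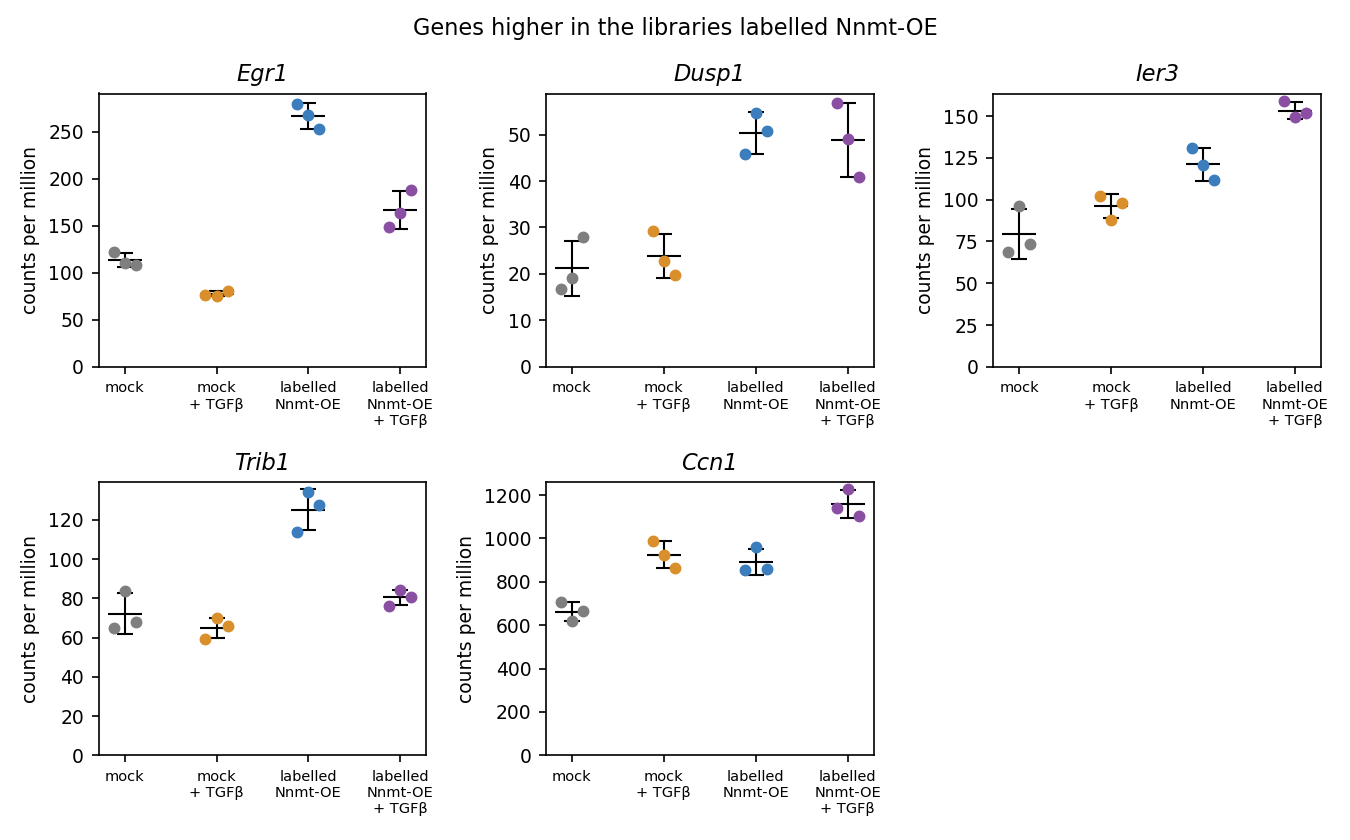
Egr1, Dusp1, Ier3, Trib1 and Ccn1 in CPM (y axes, from 0) in each library by group (x axes), with points for libraries and bars for the mean ± SD of 3. Egr1 went from 113.7 to 266.6 CPM between mock and labelled Nnmt-OE, and from 77.7 to 166.9 CPM with TGFβ.

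The same contrast was made between cells that had received TGFβ. Egr1 (2.15-fold, edgeR adjusted p = 1.43e-08), Ier3 (1.6-fold, edgeR adjusted p = 0.0119) and Dusp1 (2.04-fold, edgeR adjusted p = 0.0261) were again higher in cells labelled Nnmt-OE, and no gene was lower. All 3 were among the 5 called without TGFβ, where independent lists would share 0.00116 genes. Trib1 stood at 0.31 and Ccn1 at 0.32 with TGFβ, neither past the threshold. The difference between the comparisons was tested as an interaction, which called no gene.

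5 lists shifted upward and 1 downward in labelled Nnmt-OE cells with TGFβ, without any member passing over all genes. Of 24 TGFβ-SMAD genes, 6 rose adjusted over the list alone, with Junb at 0.41 (median 0.12, camera adjusted p = 0.000225, adjusted p = 0.0297 with an estimated correlation). Of 25 YAP-TEAD targets, 2 rose adjusted over the list alone, with F3, the tissue factor gene, at 0.42 (median 0.12, camera adjusted p = 0.00241, adjusted p = 0.041 with an estimated correlation). Among 24 mesenchymal and contractile genes, 2 rose adjusted over the list alone, the smooth muscle actin gene Acta2 at 0.65 and the actin-binding gene Tagln at 0.48 (median 0.13, camera adjusted p = 0.00887, adjusted p = 0.0586 with an estimated correlation). Extracellular matrix genes, 32 measured, had 1 call adjusted over the list alone, Thbs1 at 0.31, with Ccn4 at 0.25 (median 0.12, camera adjusted p = 0.0093, adjusted p = 0.126 with an estimated correlation). The 35 secretory genes had 2 calls adjusted over the list alone, with Cxcl1 at 0.56 (median 0.10, camera adjusted p = 0.0093, adjusted p = 0.0586 with an estimated correlation). The 4 measured genes of other nephron segments had a median of -0.14 and 1 lower call adjusted over the list alone, the claudin gene Cldn19 (-3.49 ± 1.12), with the collecting duct factor gene Tfcp2l1 at -0.14 (camera adjusted p = 0.0386, adjusted p = 0.126 with an estimated correlation). Cdkn1a and Cdkn2a stood at 0.12 and -0.15. Ribosomal protein messengers had a median of -0.10 (camera adjusted p = 0.153) and mitochondrial transcripts of -0.11 (0.192), with 0 calls by either adjustment. Among lists not called, median, mean and test differed in sign for tubular injury, p53, hypoxia and podocyte genes.

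The count of 3 went to 1, Egr1, without mock with TGFβ replicate 2 or 3, or without Nnmt-OE with TGFβ replicate 1 or 2 (highest adjusted p 0.713 for Dusp1 and 0.421 for Ier3). The matrix call ended without mock with TGFβ replicate 1 (adjusted p = 0.153) or 2 (0.163) or Nnmt-OE with TGFβ replicate 1 (0.218), the secretory call without replicate 1 of either TGFβ group (0.139 and 0.13), and the nephron segment call held in 4 of 12 such fits (highest adjusted p 0.212, without Nnmt-OE with TGFβ replicate 1). Without the immediate-early genes, the TGFβ-SMAD, YAP-TEAD and secretory calls held at the preset correlation (camera adjusted p = 0.0414 each). Their medians were then 0.05, 0.09 and 0.10, against 0.12, 0.12 and 0.10 with all members.

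TGFβ changed 184 of 12897 genes in mock cells, 86 higher and 98 lower, with 33 past 2-fold. Among the fixed lists, mesenchymal and contractile genes and TGFβ-SMAD response genes shifted upward by camera, and Id genes and NRF2 genes downward. Their medians were 0.145, 0.075, -0.357 and -0.04 in that order. Only 13 of 24 TGFβ-SMAD genes had positive values, and 16 of 38 NRF2 genes did, so these 2 shifts were not shared by most members. Acta2 rose 3.9-fold (edgeR adjusted p = 1.06e-09), from 15 ± 2.6 to 58.7 ± 5.8 CPM (SD, n = 3). The matricellular gene Postn rose 3.93-fold (edgeR adjusted p = 2.41e-05). The methyltransferase gene Inmt, which like Nnmt uses S-adenosylmethionine, fell 4.87-fold (edgeR adjusted p = 1.91e-06), from 33.1 ± 9.1 to 6.89 ± 3.18 CPM. Other genes with large rises were Fam198b (2.97-fold), the cytochrome P450 gene Cyp1b1 (2.48-fold), Ccn5 (2.45-fold), the clock factor gene Arntl (2.34-fold), the cardiac troponin gene Tnnt2 (2.33-fold), Cpne8 (2.33-fold) and the lectin gene Siglecg (2.19-fold). Large falls were seen for the receptor kinase gene Mertk (3.96-fold), the adenosine receptor gene Adora1 (2.56-fold), Abi3bp (2.45-fold), the complement gene C3 (2.39-fold), the cyclooxygenase gene Ptgs1 (2.32-fold), Sned1 (2.3-fold) and Ston2 (2.18-fold).

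Signalling and structural lists moved as follows in mock cells with TGFβ. Of 24 TGFβ-SMAD genes 4 rose, 1 fell and 19 did not pass, with 5 higher and 1 lower adjusted over the list alone. Pmepa1, a feedback inhibitor, rose by 1.01 (log2) and Pdgfb by 0.63, while Ltbp3, which binds latent TGFβ, fell by 0.63 (camera adjusted p = 2.23e-05). Of the 4 Id genes, inhibitors of differentiation driven by BMP, 2 fell by both adjustments, Id4 at -1.11 and Id2 at -0.47 (camera adjusted p = 0.00158). Of 32 matrix genes 3 rose and 0 fell, with 7 higher and 1 lower adjusted over the list alone, including Ccn4 at 0.65 and the metalloproteinase inhibitor gene Timp3 at 0.34 (camera adjusted p = 0.00315). Of 24 mesenchymal and contractile genes 5 rose, and 6 adjusted over the list alone, among them Tagln at 1.12, Actn1 at 0.57 and Tpm1 at 0.33 (camera adjusted p = 8e-07). Of 25 YAP-TEAD targets 3 rose, with 5 higher and 2 lower adjusted over the list alone: Gadd45b at 0.98, Ccn2 at 0.95 and Ccn1 at 0.48 (camera adjusted p = 0.00132). Of 35 secretory genes 2 rose, among them the activin subunit gene Inhba at 0.77, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00551). Of 20 junction and keratin genes 1 fell, the kidney cadherin gene Cdh16 at -0.68, with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0487, adjusted p = 0.0902 with an estimated correlation). Proximal tubule and other nephron segment lists each had 1 member that fell, Aqp1 at -0.54 and Tfcp2l1 at -0.49, and 1 and 2 lower adjusted over the list alone (camera adjusted p = 0.12 and 0.0721). Of 28 tubular injury genes 1 fell, the regenerative factor gene Sox9 at -0.78, with 3 higher and 2 lower adjusted over the list alone. That list had a median of 0.01, a mean of -0.08 and a test direction of down (camera adjusted p = 0.935).

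Metabolic and stress lists followed. Of 38 NRF2 and oxidative stress genes 5 fell and 1 rose, with 3 higher and 7 lower adjusted over the list alone. Gstm1, a glutathione transferase gene, fell 2.18-fold, Gstm2 fell 2.06-fold, the glutathione peroxidase gene Gpx3 stood at -0.45 and the transketolase gene Tkt at -0.42 (camera adjusted p = 0.00326). Of 27 fatty acid oxidation genes 1 fell, the thioesterase gene Acot2 at -0.74, and 2 adjusted over the list alone, with Ppargc1a at -0.45 (camera adjusted p = 0.0109, adjusted p = 0.0852 with an estimated correlation). Of 29 hypoxia and glycolysis genes 1 fell, Ndrg1 at -0.73, and 3 adjusted over the list alone (camera adjusted p = 0.00315). Of 39 p53 and arrest genes 0 passed, and 4 fell adjusted over the list alone, with Trp53inp1 at -0.44 (camera adjusted p = 0.0104). Of 55 cell cycle genes 1 rose by both adjustments, the mitotic kinase gene Cdk1 at 0.51 (camera adjusted p = 0.00158). Cholesterol synthesis (27 genes, Hsd17b7 at 0.49) and one-carbon metabolism (34 genes, Psph at 0.54) shifted upward with 0 members passing by either adjustment. Their camera adjusted p-values were 0.00925 and 0.0367, and their adjusted p-values with an estimated correlation were 0.135 and 0.0598. NAD metabolism had 0 calls and 2 lower adjusted over the list alone, with the nicotinamide salvage gene Nampt at -0.40 (camera adjusted p = 0.0578). Of 51 interferon genes 1 fell by both adjustments, the class I antigen gene H2-K1 at -0.42, with a median of 0.01, a mean of 0.04 and a test direction of down (camera adjusted p = 0.843). Of 37 unfolded protein and stress genes Asns rose (0.60) and Ddit3 fell (-0.48), with 2 higher and 1 lower adjusted over the list alone, a median of 0.01, a mean of -0.01 and a test direction of up (camera adjusted p = 0.864).

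Ribosomal protein messengers moved with TGFβ as well. In mock cells 2 of 29 rose, Rps2 (0.45) and Rps14 (0.34), and 7 adjusted over the list alone, with a median of 0.23 (camera adjusted p = 8.67e-07, adjusted p = 0.0209 with an estimated correlation). Their median kept its sign under both other scalings, at 0.23 in each. The mitochondrial transcripts, 7 measured, had a median of 0.06 and 1 higher call adjusted over the list alone, against 0 over all genes (camera adjusted p = 0.159). Markers of other cell types gave camera adjusted p-values of 0.0815 for fibroblasts and pericytes (2 measured), 0.401 for endothelium (4), 0.739 for leukocytes (3) and 0.935 for podocytes (5), with 0 calls by either adjustment. The podocyte list had a median of 0.01 and a mean of -0.04. Genes with close copies, such as Acta1 and Acta2, Gstm1 and Gstm2, the H2 genes and ribosomal protein genes with pseudogenes, may share reads, and how such reads were counted is not given in the sources used here.

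The count of 184 fell to 115 without mock with TGFβ replicate 1, to 98 without replicate 2 of that group, and to 92 in the fit of these groups alone. Of the genes named, Fam198b, Cyp1b1, Arntl, Cpne8, Siglecg, Mertk, Adora1, Ptgs1, Id4, Id2, Timp3, Tpm1, Cdh16, Cdk1, H2-K1, Tkt, Ddit3, Acot2, Ccn2, Rps2 and Rps14 lost their call in at least 1 fit without 1 library, the highest adjusted p being 0.231 for Ddit3 without mock with TGFβ replicate 1, and Sox9 lost its call without the 3 libraries that stand apart (0.0827). The junction call ended without mock replicate 1 (adjusted p = 0.114) or 3 (0.102) or mock with TGFβ replicate 3 (0.178), the one-carbon call without mock replicate 2 (0.0573) or 3 (0.157) or mock with TGFβ replicate 1 (0.0869), and the fatty acid call without mock with TGFβ replicate 2 (0.0853).

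In cells labelled Nnmt-OE, TGFβ changed 180 genes, 84 higher and 96 lower, with 29 past 2-fold. The skeletal actin gene Acta1 rose 7.29-fold (edgeR adjusted p = 0.00049), from a low 1.38 ± 0.28 CPM to 10.2 ± 5.65 CPM (SD, n = 3). Acta2 rose 5.27-fold (edgeR adjusted p = 8.83e-13), from 17.4 ± 1.5 to 91.6 ± 16.8 CPM, and Tagln rose 3.38-fold (edgeR adjusted p = 1.93e-13). Inmt fell 4.89-fold (edgeR adjusted p = 3.27e-06), from 25.3 ± 3.7 to 5.12 ± 0.71 CPM. Postn (3.25-fold), Cpne8 (2.89-fold), Cyp1b1 (2.45-fold), Fam198b (2.42-fold), Siglecg (2.39-fold) and the adaptor gene Sorbs2 (2.31-fold) also rose. Falls were seen for Scel, a gene of the cornified envelope (4.39-fold), the lipopolysaccharide-binding gene Lbp (2.63-fold), the cytokine receptor gene Il17rb (2.62-fold), the angiotensinogen gene Agt (2.52-fold), the prostaglandin D synthase gene Ptgds (2.46-fold), Trim12c (2.45-fold), Abi3bp (2.4-fold) and Gstm1 (2.37-fold).

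By camera adjusted p, structural lists in labelled Nnmt-OE cells were led by contractile genes, though matrix genes had the larger median (0.25 against 0.18). Of 24 mesenchymal and contractile genes 5 rose, and 7 adjusted over the list alone, with Actn1 at 0.61 and Tagln2 at 0.53 (camera adjusted p = 6.49e-13). Of 32 matrix genes 5 rose, with 12 higher and 2 lower adjusted over the list alone, including Ccn4 at 0.69, the thrombospondin gene Thbs1 at 0.49 and Timp3 at 0.37 (camera adjusted p = 2.29e-07). Of 24 TGFβ-SMAD genes 4 rose and 1 fell, with 5 higher and 2 lower adjusted over the list alone, led by Pmepa1 at 0.94, Pdgfb at 0.60 and Ccn2 at 0.98 (camera adjusted p = 1.51e-06). Positive values were seen for 17 of the 24, with a median of 0.109. Of the 4 Id genes Id4 (-1.02) and Id2 (-0.52) fell by both adjustments (camera adjusted p = 0.00146). Of 25 YAP-TEAD targets 2 rose, one of them Ccn1 at 0.38, and Myof fell (-0.33), with 7 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000969). Of 35 secretory genes 3 rose, among them Inhba (0.82) and the macrophage growth factor gene Csf1 (0.43), and 2 fell, the plasminogen activator gene Plat (-0.69) among them, with 3 higher and 4 lower adjusted over the list alone. That list had a median of -0.01, a mean of 0.15 and a test direction of up (camera adjusted p = 0.0167). Of 12 proximal tubule genes 1 fell, Aqp1 at -0.66, and 2 adjusted over the list alone (camera adjusted p = 0.0467, adjusted p = 0.0932 with an estimated correlation). Of 4 genes of other segments Tfcp2l1 fell (-0.44) by both adjustments (camera adjusted p = 0.0167, adjusted p = 0.061 with an estimated correlation). Of 20 junction genes 1 fell by both adjustments, Cdh16 at -0.58 (camera adjusted p = 0.132). Of 28 injury genes 4 rose and 2 fell, with 4 higher and 4 lower adjusted over the list alone. The injury marker gene Havcr1 rose by 0.91 and the lipid droplet gene Plin2 by 0.51, and the list had a median of 0.03, a mean of -0.08 and a test direction of up (camera adjusted p = 0.747).

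Metabolic and stress lists moved in both directions. Of 39 p53 and arrest genes 2 fell, Trp53inp1 (-0.52) and the death receptor gene Eda2r (-0.50), and 5 adjusted over the list alone (camera adjusted p = 2.34e-05). Ppargc1a fell 1.88-fold (edgeR adjusted p = 6.32e-06), from 174.7 ± 19.2 to 92.7 ± 6.33 CPM. It was the 1 gene to fall among 27 of fatty acid oxidation and the 1 among 22 of NAD metabolism, with 2 lower adjusted over the list alone in each and Nampt at -0.38. Camera gave adjusted p = 0.000969 for the first list and 0.0242 for the other, the latter with adjusted p = 0.1 with an estimated correlation. Of 38 NRF2 genes 5 fell, and 8 adjusted over the list alone, with Gstm2 at -0.85, the epoxide hydrolase gene Ephx1 at -0.46 and the ferritin gene Fth1 at -0.30 (camera adjusted p = 0.00146). The median of that list was -0.024, and 18 of the 38 had positive values. Ndrg1 (-0.74) was the 1 of 29 hypoxia genes to fall, and 4 did adjusted over the list alone (camera adjusted p = 0.01). Cholesterol synthesis shifted upward with 0 calls by either adjustment (camera adjusted p = 0.0061, adjusted p = 0.125 with an estimated correlation). Cell cycle genes had 1 that fell by both adjustments, Ccnd1 at -0.34 (camera adjusted p = 0.0943). One-carbon genes had 0 calls by either adjustment (camera adjusted p = 0.159). Isg15 (0.64) rose among 51 interferon genes and Vldlr (-0.43) fell among 37 stress genes, each by both adjustments (camera adjusted p = 0.215 and 0.239).

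The ribosomal protein messengers also rose in labelled Nnmt-OE cells, 2 of 29 over all genes, Rps2 (0.44) and Rpl8 (0.34), and 12 adjusted over the list alone (median 0.28, camera adjusted p = 1.47e-07, adjusted p = 0.00727 with an estimated correlation). Their median was 0.28 with RLE scaling and 0.26 with library totals. Mitochondrial transcripts had a median of -0.10 and 0 calls (camera adjusted p = 0.394). The 2 measured fibroblast markers shifted upward (camera adjusted p = 0.00589, adjusted p = 0.075 with an estimated correlation), with 0 calls over all genes and both adjusted over the list alone. The collagen gene Col1a1, a matrix gene on 2 lists, went from 3.53 ± 2.3 to 10.7 ± 2.43 CPM (edgeR adjusted p = 0.0898). Endothelial, leukocyte and podocyte markers had camera adjusted p-values of 0.228, 0.776 and 0.42, with 1 podocyte gene lower adjusted over the list alone. For endothelial markers the median was -0.01 against a mean of 0.42, and for leukocyte markers 0.05 against -0.00.

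Without mock replicate 1 the count of 180 went to 305, without Nnmt-OE replicate 1 or 3 to 109 or 97, without Nnmt-OE with TGFβ replicate 1, 2 or 3 to 104, 99 or 104, and in the fit of these groups alone to 351. Of the genes named, Cyp1b1, Fam198b, Scel, Lbp, Il17rb, Agt, Trim12c, Ccn2, Id4, Timp3, Cdh16, Tfcp2l1, Csf1, Havcr1, Plin2, Myof, Trp53inp1, Eda2r, Plat, Ccnd1, Isg15, Ephx1, Fth1, Vldlr, Ccn1, Rps2 and Rpl8 lost their call in at least 1 fit without 1 library (highest adjusted p 0.299, Isg15 without Nnmt-OE replicate 3). The proximal tubule call held in 1 of 12 such fits. The other segment call ended without Nnmt-OE replicate 2 (adjusted p = 0.0628), the cholesterol call without Nnmt-OE with TGFβ replicate 3 (0.0772), and the secretory call without Nnmt-OE replicate 3 (0.073) or Nnmt-OE with TGFβ replicate 1 (0.0583).

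The last question was whether the response to TGFβ differed with the construct. 42 genes rose in both mock and labelled Nnmt-OE cells and 48 fell in both, where independent lists would share 0.56 and 0.729, and 0 were called in opposite directions. Of the 86 and 98 genes called higher and lower in mock, 85 and 96 had the same sign in labelled Nnmt-OE cells. These comparisons share no library. Across the 12897 genes, which are not independent replicates, the log2 fold changes had Pearson's r of 0.231 and Spearman's rho of 0.264, against r of -0.034 to 0.048 in simulated unchanged groups. Without 1 library that r was 0.147 to 0.19, the lowest without Nnmt-OE replicate 3 (0.147) or Nnmt-OE with TGFβ replicate 3 (0.149). Genes were filtered anew in each fit without 1 library, with 1 group smaller, so those values are not over the same 12897 genes. In the full fit, r over genes at 10 CPM or more was 0.43. The construct effects with and without TGFβ had an r of 0.069, against -0.031 to 0.027 in simulated groups, and of 0.033 to 0.069 without 1 library, the lowest without mock replicate 1 (0.044) or Nnmt-OE with TGFβ replicate 1 (0.033) or 2 (0.041). Simulated genes varied independently of each other, so chance may give a wider range of r in real libraries. Whether an r of 0.069 exceeds chance is therefore not decided.

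The interaction test called 0 genes with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 0 with DESeq2 and 0 with limma-voom, and 501 genes had an unadjusted p under 0.05 where 645 are due by chance. Tagln had the interaction estimate 0.64 ± 0.17 and Acta2 0.44 ± 0.25 (log2 ± SE, edgeR adjusted p = 0.999 for each). No list was called for the interaction, and 1 gene, Tagln, passed adjusted over the list alone, with the smallest camera adjusted p of 0.371, for matrix genes and for mitochondrial transcripts. Without mock replicate 3, 1 list was called lower, the mitochondrial transcripts. The interval of an interaction estimate reached 0.5 to either side at the median for genes at 10 CPM or more. The mean effect of the construct and the mean effect of TGFβ had r of 0.053 and rho of 0.094 across genes, with a covariance of 0.00647 against 0.00162 ± 0.0014 (SD of 10 draws) in simulated unchanged groups. Leaving out 1 library moved that r to between -0.167 and 0.235, negative without any library of mock with TGFβ or of Nnmt-OE. Uneven groups give the construct and TGFβ effects a shared chance covariance, so that range does not test the r. Simulated genes varied independently of each other, so whether an r of 0.053 exceeds chance is not decided. No direction is drawn from that r.

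**Figure D3:**
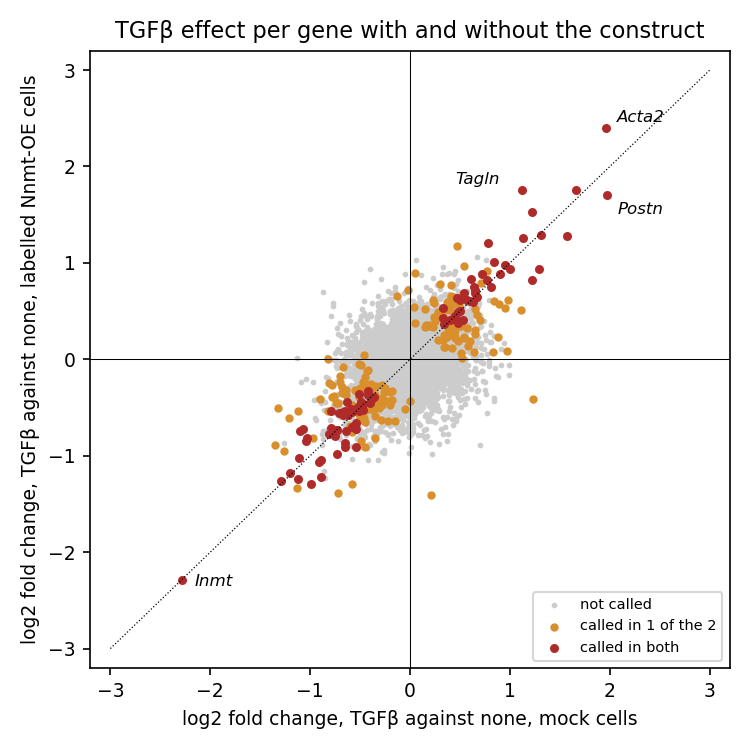
Each point is a gene with a mean of 10 CPM or more, at its log2 fold change with TGFβ in mock cells (x axis) and in labelled Nnmt-OE cells (y axis). Red points were called in both, orange points in 1, grey points in neither, and the dotted line marks equal effects, with Acta2 at 1.96 and 2.40 and Inmt at -2.28 and -2.29.

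**Figure D4:**
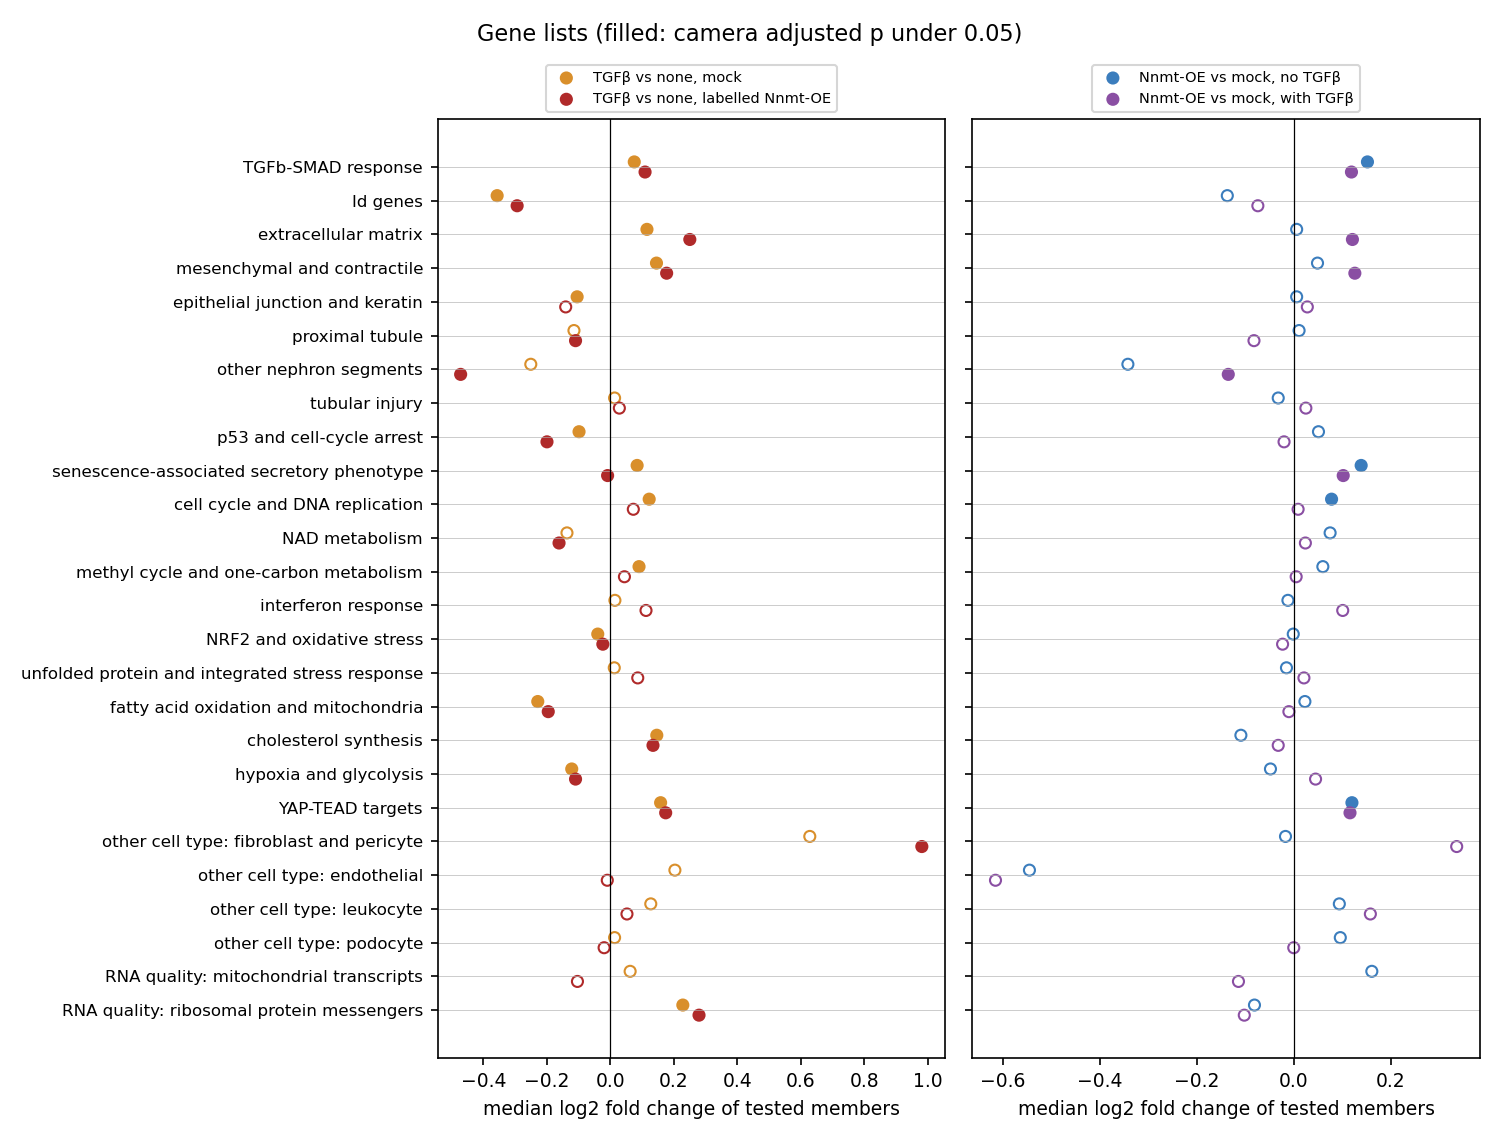
Median log2 fold change of the measured members (x axes, on different scales) of each of the 26 lists, for TGFβ against none (left) and labelled Nnmt-OE against mock (right). Filled points had a camera adjusted p under 0.05, and ribosomal protein messengers lie at 0.23 and 0.28 with TGFβ.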

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

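The alternatives below were planned except the fit without the 3 libraries that stand apart, which was chosen after the results were seen. For labelled Nnmt-OE against mock without TGFβ, 5 genes became 13 without a filter (9 higher, 4 lower, all 5 kept), 3 with the groups compared only, 2 past 2-fold and 3 to 6 without 1 library. For TGFβ in mock cells, 184 became 92 with the groups compared only, 290 with DESeq2 (177 of the 184 kept), 33 past 2-fold and 98 to 188 without 1 library. For TGFβ in labelled Nnmt-OE cells, 180 became 351 with the groups compared only, 274 with DESeq2, 29 past 2-fold and 97 to 305 without 1 library. For labelled Nnmt-OE against mock with TGFβ, 3 became 2 past 2-fold, 4 without a filter and 1 to 3 without 1 library. The interaction count stayed at 0 in every alternative run. The cause of these moves was not tested. Lists called went from 6 to 2 with an estimated correlation and 3 with fry for the construct with TGFβ. Without 1 library they ranged from 2 to 5 for the construct without TGFβ and 3 to 7 with it, from 14 to 17 and 14 to 16 for TGFβ in mock and labelled Nnmt-OE cells, and from 0 to 1 for the interaction. The r between the TGFβ effects was 0.43 for genes at 10 CPM or more, 0.147 to 0.19 without 1 library and 0.149 without the 3 libraries that stand apart. Fits that leave out libraries filtered the genes anew, so their genes were not the same. The r between the construct and TGFβ main effects ranged from -0.167 to 0.235 without 1 library. Uneven groups give these effects a shared chance covariance, so that range does not test the r. Without the 3 libraries that stand apart the gene counts were 4, 168, 260, 3 and 0 for the comparisons in the order above, the interaction last. That fit ended the calls of Ier3 (without TGFβ, adjusted p = 0.197), of Arntl (0.422), Mertk (0.222), Sox9 (0.0827), H2-K1 (0.0667), Ddit3 (0.0571), Acot2 (0.156) and Pdcd4 (0.0835) in mock, and of Agt (0.114), Trim12c (0.065), Eda2r (0.0555) and Vldlr (0.0605) in labelled Nnmt-OE cells. It also ended the list calls of cell cycle for the construct without TGFβ (adjusted p = 0.203), other nephron segments with TGFβ (0.258), junctions for TGFβ in mock (0.262) and cholesterol in labelled Nnmt-OE cells (0.0829). For the construct with TGFβ that fit added camera calls of ribosomal protein messengers, lower (adjusted p = 0.0214), and unfolded protein genes, higher (0.0297). For TGFβ in mock it added NAD metabolism, lower (camera adjusted p = 0.0165). The replicate numbers did not pair the samples: deviations of same-number pairs correlated at -0.102 to 0.047, those of 36 other pairs at -0.066 to 0.086, and 4 of 12 libraries correlated best with their own number. With the replicate block the counts were 4, 170, 168, 3 and 0 for the comparisons in that order with the interaction last, and the lists called 4, 15, 15, 6 and 0. Of 182 gene results with their comparison, 137 were called. Of these, 132 kept their call under RLE scaling, library totals, DESeq2 and the block, wherever these gave an adjusted p. The other alternatives that leave out no library, the 2-fold threshold among them, were not part of that count. With the block alone 132 kept their call, in all fits without 1 library 78 did, and 0 reversed. The block ended the calls of Ier3 (without TGFβ, adjusted p = 0.0534), Cdk1 (0.0912) and Rps14 (0.0528) in mock, and Fth1 (0.0576) and Vldlr (0.0556) in labelled Nnmt-OE cells. Nnmt, not called for TGFβ in labelled Nnmt-OE cells, ranged from -0.054 to 0.251 without 1 library, the lowest, a reversed sign, without Nnmt-OE with TGFβ replicate 1.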

Other observations

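The tests of exchanged labels, of the construct's 3' end, of library handling, of the wider immediate-early list and of depth were chosen only after the results were seen, as were the genes named in the next paragraph. The tests of single libraries, of lists without immediate-early genes, of matched random lists and of other splits were written down after the patterns were seen and before their own results.

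Of the 90 genes called with TGFβ in both mock and labelled Nnmt-OE cells, 64 were on no list. They are named singly, since no list or test covers them as groups. The sodium pump subunit gene Atp1b1 fell, at -0.73 in both (edgeR quasi-likelihood adjusted p = 4.46e-08 and 3.16e-08), and so did the ceruloplasmin gene Cp, at -0.79 and -0.71. Klf4 (-0.65 and -0.53), Maf (-0.54 and -0.91), the nuclear receptor gene Rora (-0.58 and -0.70) and Mxd4, a partner of MAX (-0.81 and -0.78), were also lower. The guidance gene Sema3c (-0.92 and -1.07), the Notch pathway ligase gene Neurl1b (-0.90 and -1.05), the thioredoxin-binding gene Txnip (-0.63 and -0.58), the translation inhibitor gene Pdcd4 (-0.54 and -0.72) and the motor gene Myo6 (-0.65 and -0.86) fell as well. The genes that rose included the secreted factor genes Fstl1 (0.67 and 0.64) and Bdnf (0.82 and 0.75), the ubiquitin hydrolase gene Uchl1 (0.90 and 0.89) and the stress gene Gadd45g (0.72 and 0.88). Egr1, higher with the construct, fell with TGFβ in both, at -0.55 and -0.68 (edgeR adjusted p = 0.00223 and 5.1e-05). Maf, Rora, Pdcd4 and Uchl1 in mock, and Bdnf, Uchl1 and Klf4 in labelled Nnmt-OE cells, lost their call in at least 1 fit without 1 library.

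With 6 libraries there are 10 splits, so no share under 0.1 can be had. The real split called 5 genes for labelled Nnmt-OE against mock without TGFβ and 3 with it, where the highest other split called 0 in each. It called 184 for TGFβ in mock cells against a highest other of 37, and 180 in labelled Nnmt-OE cells against 0. In each, 1 of the 10 splits, the real one, reached its count. For the interaction the real count is 0, which every split must reach (100 of the 100 drawn from 200), so these splits decide nothing about chance. 5 of them called any gene, the highest 88, which points to a structure of the samples whose cause was not tested.

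Nnmt counts did not pass the test in the libraries labelled Nnmt-OE. An exchange of labels between the construct groups was looked for in the mock over Nnmt-OE fold, whose upper 95% bound was 1.48 at most. The upper bound of the Nnmt-OE over mock fold was 1.69 without TGFβ and 1.22 with it. Neither order of the labels came with clearly raised Nnmt, so these bounds cannot tell exchanged labels from the labels as given. A construct whose transcripts end outside the counted 3' end may account for it. The share of reads given to no gene was 27.66 ± 0.82% with and 27.48 ± 0.84% without the construct (SD, n = 6), a difference of 0.18 percentage points that decides nothing, since reads in vector sequence need not map. A construct that did not raise the messenger stays open too, untested.

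The genes higher with the construct were immediate-early genes. Without TGFβ, no single library accounts for 3 of the 5, Egr1, Dusp1 and Trib1, which stayed called without any 1 library. Ier3 kept its call in 4 of 12 such fits and Ccn1 in 8. With TGFβ only Egr1 stayed called in all 12, while Dusp1 and Ier3 held in 7 each. A list of 54 immediate-early genes, without those called, shifted upward without TGFβ (39 of 44 positive, median 0.31, camera p = 3.63e-15, and p = 1.33e-05 with an estimated correlation) and with it (37 of 46, median 0.31, p = 4.65e-14 and 1.73e-05). That list was drawn up after the results were seen. Genes already high but not called, such as Junb and Cxcl1, stayed in it. These p-values are therefore no independent support for a wider response. Without immediate-early genes 0 of 3 lists stayed called in untreated cells (TGFβ-SMAD and secretory, adjusted p = 0.0663 each, and YAP-TEAD, 0.155; medians 0.15 to 0.13, 0.14 to 0.10 and 0.12 to 0.09), and with TGFβ all 3 passed at the preset correlation (0.0414 each; medians 0.12 to 0.05, 0.10 to 0.10 and 0.12 to 0.09), though the secretory list with all members had already missed at an estimated correlation (adjusted p = 0.0586). The medians in untreated cells kept most of their size over fewer genes, so whether immediate-early genes carried those shifts stays open. Such genes also respond to handling, and with 0 mock library codes between those of the construct libraries, handling and construct cannot be told apart.

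Ribosomal protein messengers were higher with TGFβ with and without the construct. Depth as the whole cause is argued against, since TGFβ libraries had 1.21 times the reads of untreated ones in mock but 0.94 times in labelled Nnmt-OE cells. For a trend with transcript length, 3' GC or abundance, 10000 matched lists were drawn, with length and GC of each gene's longest annotated transcript. Among them the medians of 0.23 and 0.28 lay at percentiles 99.99 and 100 (matched medians 0.02 in each). Lists drawn gene by gene leave out that ribosomal protein genes may vary together, so the percentiles may be too high. The matched medians argue against a trend with abundance or these annotated values as the whole cause. A trend with the transcripts actually counted stays open. Reads shared with pseudogenes and a response to TGFβ were not tested and stay open. Since codes of TGFβ and untreated libraries do not interleave, handling cannot be told apart from TGFβ here either.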
